A study of Mus musculus with 12 samples.

How the data were processed

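Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in hepatocytes from 12 mice. Each mouse gave 1 library, and per the labels the 3 mice of a group are separate animals. Of the 4 groups, floxed controls carried Fbxl5 alleles flanked by recombination sites without Cre, and Fbxl5-deleted mice carried the same alleles with a Cre recombinase driven by the albumin promoter. Mice of each genotype received a standard diet or a diet with 0.1% DDC (3,5-diethoxycarbonyl-1,4-dihydrocollidine, which causes porphyrin accumulation and cholestasis) for 2 weeks. Nuclei came from hepatocytes separated by collagenase perfusion, a preparation that can hold other liver cells.

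The submitters' processing notes name fastp, Bowtie2, SAMtools, Picard, bedtools, deepTools and MACS2, with no versions, and the mouse build mm10; the order and settings of these tools, and any shift of read positions for the transposase, are not given in the sources used here. The deposited files are peak lists, 1 per library, so the authors called peaks per sample and did not pool replicates. In each deposited list the fold enrichment (a ratio) is the peak's height over the background that the caller estimated within the same library, with no separate control library. The deposited −log10 p and −log10 q values are the caller's own, and the smallest −log10 p corresponds to a p-value threshold of 0.05 in every list. The score in the deposited lists is the whole part of 10 times the −log10 p. The summit position in the deposited lists was not used. The lists hold no read counts, so the depth of a library is known only through its peaks; at weak peaks the fold enrichment moves in equal steps, from which the background height in fragments was inferred for each library.

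Peaks on chromosomes 1 to 19, X and Y were used, and several summits of 1 peak were merged. List lengths differed, so the strongest 137034 peaks by fold enrichment were kept in each library, the number in the shortest list. Ties in fold enrichment were ordered by −log10 p and then by chromosome and position. In Fbxl5-deleted standard-diet libraries 1 and 3 the lowest kept fold enrichment (2.45 and 2.29) was also the median of the full list. The cut there fell among many equal weak peaks, so which of them were kept depended in part on position. Kept peaks of all libraries were merged where they overlapped by at least 1 bp (bedtools 2.31.1), giving 291982 regions, of which 138620 were kept in at least 3 of the 12 libraries and were tested. A region's value is its rank within its own library mapped to the mean distribution of log2 fold enrichment over the 12 libraries. A region absent from a list took the lowest value, log2 1.28, so a difference against a group in which it was absent from all 3 lists has no true size and is given as the number of lists that hold it. Where it was absent from 1 or 2 lists, the difference rests in part on that value. Because of the ranking, differences are relative to the other regions of a library, and a change of all regions alike would not be seen. The median difference over all tested regions lay between −0.03 and 0.00 log2 in the 5 comparisons.

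Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend and robust settings) on all 12 libraries with 4 group means and no covariates; p-values were two-sided, adjusted by the Benjamini-Hochberg method, and regions with an adjusted p under 0.05 were called. The comparisons were diet within each genotype, genotype within each diet, and the difference of the diet effects. Values of whole libraries were compared by two-sided exact permutation tests, adjusted by the Benjamini-Hochberg method over the 39 that had strata; this adjustment was added after the data were seen. With 3 libraries against 3 the smallest p such a test can give is 0.1, and with both diets or both genotypes kept as strata (400 relabellings) it is 0.005. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and GenomicRanges 1.54.1 were used.

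The annotation table in use (GRCm38.p6, the assembly of mm10) gives the start and end of each gene without strand or exons. Each region was therefore assigned to the shortest protein-coding gene whose span it overlaps, or otherwise to the nearest within 50 kb, in place of the nearest transcription start planned before the data were examined; 12.2% of tested regions had no gene. Likewise the planned promoter share became the share of peaks within 1 kb of either end of a gene. Whether a region is exonic or intronic is not known here. No genome sequence was used, so the 37 transcription factor motifs planned were not scanned.

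Regions of 20 gene lists were tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists) and again with the correlation estimated from the data. The lists were iron handling, antioxidant (NRF2 targets), heme synthesis and breakdown, bile acid synthesis, bile acid transport and receptors, hepatocyte identity, inflammation and acute phase, AP-1 and immediate early genes, cell cycle and p53 targets, ER stress with amino acid response and ferroptosis, lipid metabolism, drug-metabolising cytochromes and transferases, pericentral zone, periportal zone, metallothionein and hypoxia, and markers of cholangiocytes, stellate cells, macrophages and myeloid cells, sinusoidal endothelium and lymphocytes. The groups, the tests, the lists, the alternatives in the closing section except those named there as later, and the rule for named regions were fixed before the data were examined. The rule took, per comparison, the 10 called regions with the largest rise and the 10 with the largest fall near a gene with a proper name, 1 region per gene, and from each list the regions of the 2 genes with the smallest p; Fbxl5 is always given. Results at 3 single genes are not reported here.

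The test was checked on simulated data for the diet comparison in floxed controls, with 200 regions each changed by a log2 of 0.5, 1 or 2 among 138620. It recovered 3, 44 and 122 of them, and 19 of its calls (10.1%) were unchanged regions. The median half-width of the 95% interval of a difference was 0.46 log2 (0.65 for the difference of diet effects). Where as few regions change as in this simulation, differences of up to about 2-fold in a single region were therefore mostly missed. Even 4-fold changes were recovered in only 61% of the regions. Where many regions change, the adjusted threshold is easier to pass. In the diet comparisons the median size of called regions was 1.03 log2 in floxed controls and 1.08 in Fbxl5-deleted mice. No pair of libraries had identical values. Alternatives were other list lengths, rankings, region definitions, filters, model settings, the replicate number as a block, each library left out in turn and, added later, pairs of libraries of 1 group left out, library covariates and a shared reference group.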

Results

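ATAC-seq peak lists were analysed from hepatocytes of 12 mice, 3 in each of 4 groups: floxed controls and mice with hepatocyte deletion of Fbxl5, each on a standard diet or on a diet with 0.1% DDC for 2 weeks. FBXL5 is the substrate-binding subunit of a ubiquitin ligase that degrades the iron regulatory protein IRP2, and DDC is a porphyrinogenic, cholestatic compound. The design asks how the accessibility of chromatin differs between the genotypes in cholestatic liver and without it. Values below are rank-based log2 fold enrichments of a region within its library, with differences ± SE from limma.

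The floxed control lists held 144733 ± 7419 peaks (SD, n = 3) on the standard diet and 192506 ± 11765 on DDC. The Fbxl5-deleted lists held 224613 ± 63636 on the standard diet and 176974 ± 12804 on DDC. Fbxl5-deleted standard-diet libraries 1 and 3 stood apart, with 262080 and 260622 peaks against 137034 to 202912 in the other 10, and with the lowest inferred background, 0.636 and 0.748 fragments against 0.877 to 1.32. Peaks with a −log10 q of at least 5 ranged from 46949 to 86745 per library and averaged 76824 on DDC and 62834 on the standard diet (difference 13989.7, exact permutation within genotype, two-sided, p = 0.005, the smallest it can give). The inferred background was also higher on DDC, at 1.15 against 0.852 fragments (p = 0.005 in the same exact permutation test). A diet effect on the number of stronger peaks therefore cannot be told apart from this difference between the libraries. For all listed peaks the diet difference was 66.7 (p = 0.995 in the same exact permutation test), and 36804.7 without the 2 libraries that stood apart (exact permutation, p = 0.025). Between genotypes within diet, the difference in peaks with a fold enrichment of at least 5 was −6428 (58466 against 64894, p = 0.04), and that in peaks with a −log10 q of at least 5 was −8312 (p = 0.06, exact permutation tests). Without the 2 libraries that stood apart these were −2661 and −2566 (p = 0.175 and 0.3625, exact permutation). Without library 1 alone the former was −4258 (exact permutation, p = 0.065), and leaving out 1 of 6 other libraries also gave p of 0.07 to 0.1. For all listed peaks the genotype difference was 32174 (p = 0.335, exact permutation), and without the 2 libraries that stood apart it was −4564. None of the 39 permutation tests of library values passed a Benjamini-Hochberg adjustment over all of them, the lowest adjusted p being 0.065. As p cannot go below 0.005 here, no test could pass alone, however large its difference, so this does not show that differences are absent.

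**Figure D1:**
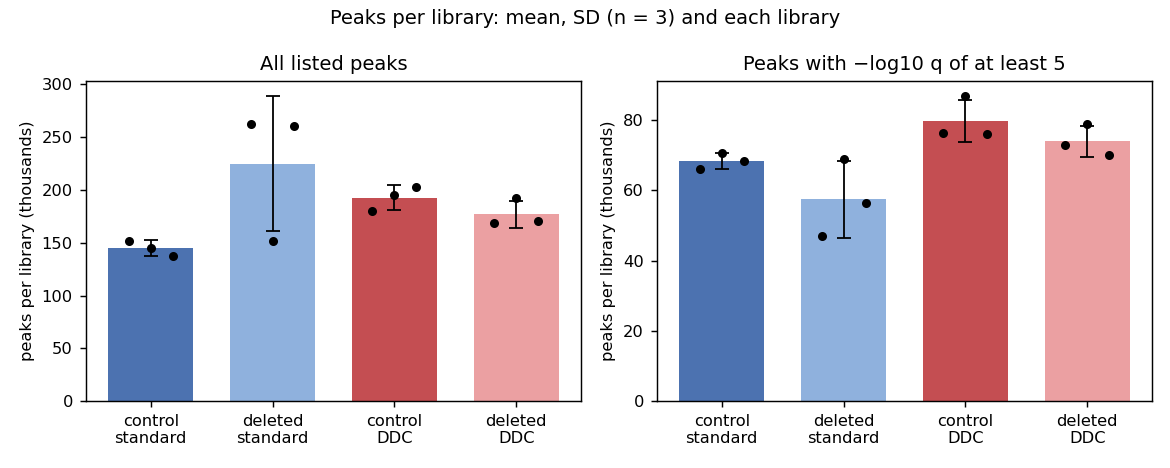
Number of peaks per library (axis divided by 1000), for all listed peaks (left) and for peaks with a −log10 q of at least 5 (right); bars are means of the 3 libraries of a group, whiskers are SD and points are libraries. Fbxl5-deleted standard-diet libraries 1 and 3 hold 262080 and 260622 listed peaks but only 46949 and 56371 at the higher threshold.

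At the targeted gene, Fbxl5 (chromosome 5, 43744618 to 43782149, mm10), a peak at the gene end (43781400 to 43782725) was listed in all 12 libraries. Its value differed between Fbxl5-deleted and control libraries by 0.19 ± 0.19 on the standard diet and −0.05 ± 0.19 on DDC, neither of which passed the test (limma, adjusted p = 0.849 and 1.0). The other Fbxl5 region tested (43745212 to 43745590) differed by −0.09 ± 0.31 and 0.04 ± 0.31. Without Fbxl5-deleted standard-diet libraries 1 and 3 the standard-diet differences turned sign, to −0.10 at the gene end and 0.087 at the other region. Which part of Fbxl5 was deleted is not given in the sources used here, so these peaks do not check the deletion.

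In floxed controls, DDC raised accessibility at 5874 regions and lowered it at 3445 of 138620 (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 1811 risers (30.8%) and 624 fallers (18.1%) were absent from all 3 lists of the lower group, so their differences have no true size. Only 3747 of the 9319 called regions were in all 12 lists. The largest rise lay within Psd3, an ARF6 exchange factor (chromosome 8, 68157180 to 68157594), at 2.91 ± 0.31 log2 (adjusted p = 1.16e-05, n = 3 against 3). It was followed by regions at Efl1, a GTPase of ribosome assembly (2.72 ± 0.25), Zscan25 (2.69 ± 0.24), the basement membrane collagen gene Col4a6 (2.67 ± 0.28) and Il33, which encodes an alarmin cytokine (chromosome 19, 29911914 to 29912438, 2.57 ± 0.28). Regions at Bloc1s6 (2.56 ± 0.26), Syt9 (2.56 ± 0.26) and Ddit4l (2.55 ± 0.25) came next, and regions near Fam3c and in Chchd3 were listed in 3 of 3 DDC and 0 of 3 standard-diet libraries. The largest fall lay in the vomeronasal receptor gene Vmn2r21 (chromosome 6, 123495751 to 123496521, −2.50 ± 0.24), before Trappc10 (−2.43 ± 0.25), the laminin gene Lama3 (−2.24 ± 0.24) and Vmn2r22 (−2.19 ± 0.24). Vmn2r21 and Vmn2r22 belong to a family of near-identical copies and are therefore uncertain. Falls also reached −2.16 ± 0.22 near Vapa, −2.08 ± 0.26 near Clp1, −2.07 ± 0.24 in Tmem45a, −2.05 ± 0.42 near Zfp280d and −2.04 ± 0.30 in Unc5c. Of the regions given here with a size, all but those at Bloc1s6, Vapa and Zfp280d were absent from 1 or 2 of the 3 lists of the lower group. Absence counts as the lowest value, so their sizes and order are approximate.

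**Figure D2:**
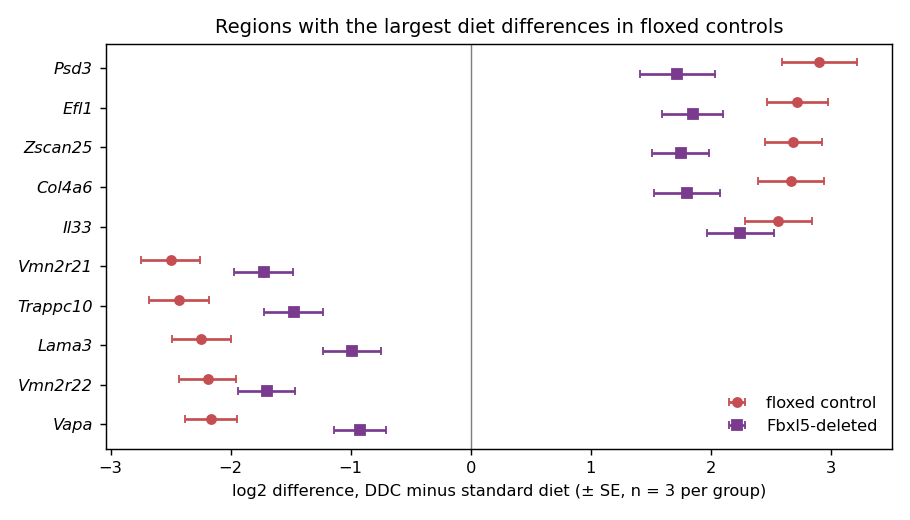
Difference between DDC and standard diet (log2, ± SE, n = 3 per group) at the 5 regions with the largest rise and the 5 with the largest fall in floxed controls, named by gene, for floxed controls (circles) and Fbxl5-deleted mice (squares). The regions were chosen for their size in controls, which favours larger values there; at Psd3 the control difference is 2.91, and the squares have the same sign as the circles at each gene.

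Among genes of bile acid handling, Atp8b1, a canalicular flippase, had a rise of 1.95 ± 0.28 at a region 31218 bp from the gene (limma, adjusted p = 0.000197). Nr1h4, which encodes the bile acid receptor FXR, had a rise of 1.45 ± 0.24 inside the gene (limma, adjusted p = 0.000637). Of the 281 regions of 21 transporter and receptor genes 9 rose and 5 fell (5 and 4 adjusted over the list alone), with no shift of the list. Of 193 regions of 14 bile acid synthesis genes 1 rose and 6 fell (1 and 2 adjusted over the list alone). The region in Cyp7b1, an enzyme of the alternative pathway, fell by 1.22 ± 0.30, a call lost without floxed control standard replicate 2 or DDC replicate 2, and that in Scp2 rose by 1.09 ± 0.24. Bile acid synthesis regions shifted down as a list (camera, adjusted p = 0.0448), with adjusted p = 0.247 with an estimated correlation and a turned direction with all deposited peaks (adjusted p = 0.884). Among 77 regions of heme genes 3 fell and 0 rose, before and after adjustment over the list alone, among them Fech, which encodes the ferrochelatase that inserts iron into heme (−1.16 ± 0.26), and the porphyrin exporter gene Abcg2 (−0.77 ± 0.15). Of 328 iron handling regions 6 rose and 5 fell (4 and 2 adjusted over the list alone). A region in Cp, which encodes the ferroxidase ceruloplasmin, fell by 1.29 ± 0.23, and a region in Bmp6, a ligand upstream of hepcidin, was listed in 3 of 3 DDC and 0 of 3 standard-diet libraries.

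Hepatocyte identity genes shifted down as a list in floxed controls (camera, adjusted p = 0.0246), with adjusted p = 0.501 with an estimated correlation. Single members went both ways: of 339 regions of 24 genes 6 rose and 4 fell (4 and 3 adjusted over the list alone). A region near Apob, the apolipoprotein of secreted lipid particles, was at −0.72 ± 0.15 and one near the pioneer factor gene Foxa1 at 1.12 ± 0.24. The Foxa1 call was lost without floxed control DDC replicate 2. Antioxidant genes also shifted down (adjusted p = 0.0372, and adjusted p = 0.247 with an estimated correlation), with 6 regions up and 9 down of 281, unchanged in number when adjusted over the list alone. Neither list passed with all deposited peaks. Here a region near Prdx1, a peroxiredoxin, rose by 0.62 ± 0.13, and one near Gclc, of glutathione synthesis, was listed in 3 of 3 DDC and 0 of 3 standard-diet libraries.

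Of 5 marker lists of other liver cells, 2 shifted with the diet in floxed controls. Macrophage and myeloid regions shifted up (camera, adjusted p = 0.0246, and adjusted p = 0.235 with an estimated correlation), but not with all deposited peaks. Of 61 regions 5 rose and 1 fell (7 and 2 adjusted over the list alone), among them Csf1r, the receptor of a macrophage growth factor (0.98 ± 0.20, but −0.90 with 50% reciprocal overlap), and the integrin gene Itgam (1.37 ± 0.27). Stellate cell and matrix regions shifted up as well (adjusted p = 0.0262, and adjusted p = 0.0918 with an estimated correlation), with the direction turned with all deposited peaks (adjusted p = 0.232). Of 84 regions 6 rose and 1 fell (8 and 1 adjusted over the list alone), such as Acta2, smooth muscle actin (1.59 ± 0.29), and Reln (1.77 ± 0.27). Sinusoidal endothelial regions had 7 up and 7 down of 140 (9 and 8 adjusted over the list alone), with Pecam1 at −1.16 ± 0.17 and an Fcgr2b region listed in 3 of 3 DDC and 0 of 3 standard-diet libraries. Cholangiocyte regions had 7 up and 9 down of 157 (10 and 9 adjusted over the list alone), with the transcription factor gene Ehf at 1.47 ± 0.21 and Anxa3 at −1.63 ± 0.22. Lymphocyte markers had 0 up and 1 down of 28, and 0 and 1 adjusted over the list alone. The Cd4 region was listed in 0 of 3 DDC and 3 of 3 standard-diet libraries. At Cd3e a region with the same pattern did not pass (adjusted p = 0.0914).

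The remaining lists did not shift in floxed controls (camera, adjusted p = 0.296 to 0.941 for the 15 lists not called). Of lipid metabolism regions 11 rose and 9 fell (6 and 4 adjusted over the list alone), with Cpt1a, the gatekeeper of mitochondrial fatty acid import, at 1.56 ± 0.23 and Acacb, an acetyl-CoA carboxylase, at −1.43 ± 0.19. Drug-metabolising genes had 6 up and 3 down on both adjustments, with regions near Cyp2b10 at 1.40 ± 0.21 and Cyp3a25 at 1.84 ± 0.32. Pericentral genes had 5 up and 0 down on both, at the Wnt feedback regulators Znrf3 (1.53 ± 0.18) and Axin2 (1.61 ± 0.31) among others. Their median was −0.01 while their mean, 0.02, and test pointed up. Periportal genes had 5 up and 1 down on both, at Igf1 (0.96 ± 0.14) and Ctsc (1.40 ± 0.25). AP-1 and immediate early genes had 11 up and 5 down (14 and 6 adjusted over the list alone). Regions near Atf3 and Klf4 were listed in 3 of 3 DDC and 0 of 3 standard-diet libraries. The median of this list was −0.06 while its mean, 0.04, and its test pointed up. Inflammation genes had 6 up and 8 down on both adjustments, with Tnfaip3, an inhibitor of NF-κB, at 1.80 ± 0.25 and the chemokine gene Cxcl2 at −1.29 ± 0.22. Cell cycle and p53 genes had 2 up and 2 down (2 and 0 adjusted over the list alone), with cyclin E1 (Ccne1) at 1.94 ± 0.25 and an Mdm2 region in 3 of 3 DDC and 0 of 3 standard-diet libraries. ER stress genes had 2 up and 2 down (0 and 2 adjusted over the list alone), with the lysosomal regulator Tfeb at −1.21 ± 0.27 and Chac1 at −1.09 ± 0.28. Metallothionein and hypoxia genes had 5 up and 8 down (7 and 11 adjusted over the list alone), with a region near Mt1 in 3 of 3 DDC and 0 of 3 standard-diet libraries and Pfkfb3 at −0.70 ± 0.16 (but 1.06 with 50% reciprocal overlap). The calls at Tfeb and Pfkfb3 were lost without DDC replicate 2 and standard replicate 3 of the floxed controls, and that at Chac1 without any of 5 libraries.

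In total, 9319 regions were called in floxed controls. Regions within 1 kb of a gene end were fewer among risers (4.97% against 14.7% of the other regions) and fallers (5.69% against 14.5%, Fisher's exact test, two-sided, adjusted p = 3.65e-121 and 3.68e-59). The test takes neighbouring regions of the same mice as independent, so these p-values are too small. The count of called regions ranged from 3151 with no filter on regions to 13732 against all 6 standard-diet libraries. It was 3714 when a peak and its merged region had to overlap by 50% both ways. Without 1 library it was 5643 (standard replicate 2), 5668 (standard replicate 3), 6057 (DDC replicate 1) and 4771 (DDC replicate 2). DDC libraries also had the higher background and kept fold enrichment, and the count was 3223 and 4335 with these as covariates.

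In Fbxl5-deleted mice, DDC raised 3045 regions and lowered 1181 (limma, Benjamini-Hochberg adjusted p under 0.05). The largest rise lay near Smad3, a mediator of TGF-β signalling (chromosome 9, 63793600 to 63794505, 2.35 ± 0.22, adjusted p = 1.25e-05). Next were regions near Ank, a pyrophosphate transporter gene (2.33 ± 0.28), Bloc1s6 (2.31 ± 0.26), B4galt6, of lactosylceramide synthesis (2.26 ± 0.30), and Fam180a (2.26 ± 0.29). Rises of 2.25 ± 0.28 near Il33, 2.24 ± 0.24 near Papss1, of sulfate donor synthesis, 2.22 ± 0.24 in Elmo1, 2.21 ± 0.27 in the translation factor gene Eif2s1 and 2.20 ± 0.27 in Cdk14 followed. The largest falls lay in Tmem45a (chromosome 16, 56847978 to 56848617, −2.06 ± 0.24), the mitochondrial carrier gene Slc25a26 (−1.94 ± 0.30), near Cstdc4 (−1.76 ± 0.26) and near Gli2, a hedgehog transcription factor (−1.75 ± 0.25). Pabpc4l, Vmn2r21, Vmn2r22, Nfib, LOC115486419 and Pinx1 had falls between −1.75 and −1.65, with 0.16 at Pinx1 in 500 bp windows. Of these regions, only those at Elmo1, Eif2s1, Gli2, Nfib and Pinx1 were in all 3 lists of the lower group, so the sizes and order of the others are approximate. With standard-diet library 2 as the only one of its group, B4galt6 (1.62, adjusted p = 0.0565), Slc25a26 (−1.45) and Cstdc4 (−1.51) did not pass. Regions at Bloc1s6, Il33, Tmem45a, Vmn2r21 and Vmn2r22 were among the 10 largest risers or fallers of both genotypes.

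Hepatocyte identity, antioxidant and bile acid synthesis genes shifted down as lists in Fbxl5-deleted mice (camera, adjusted p = 0.00148, 0.00377 and 0.0120, and adjusted p = 0.263, 0.128 and 0.128 with an estimated correlation). With all deposited peaks none of them passed, and antioxidant and bile acid synthesis genes turned direction (adjusted p = 0.974 and 0.614). Of hepatocyte identity regions 2 rose and 2 fell (1 and 1 adjusted over the list alone), with the nuclear receptor gene Nr5a2 at 0.79 ± 0.14 and the fibrinogen gene Fgb at −1.12 ± 0.26. Of antioxidant regions 1 rose and 4 fell (1 and 2 adjusted over the list alone), with Gstp1, a glutathione transferase, at −1.06 ± 0.19 and catalase (Cat) at −1.31 ± 0.28. Of bile acid synthesis regions 1 rose and 1 fell, and 0 and 0 adjusted over the list alone. The Scp2 region was listed in 3 of 3 DDC and 0 of 3 standard-diet libraries. A Cyp7b1 region at −0.95 ± 0.28 did not pass (adjusted p = 0.0699). Without the standard-diet libraries 1 and 3 that stood apart, 1 standard-diet library is left, assumed to vary like the other groups. There the 3 lists did not pass (adjusted p = 0.806, 0.446 and 0.446), with medians of −0.04, −0.04 and −0.05 in place of −0.15, −0.14 and −0.11. The Gstp1, Cat, Nr5a2 and Fgb regions did not pass either, at −0.98, −0.84, 0.49 and −1.08, nor did that of Scp2. The calls at Cat, Fgb and Scp2 were also lost without at least 1 single library.

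The other 17 lists did not shift in Fbxl5-deleted mice (camera, adjusted p = 0.0674 to 0.724). Macrophage regions had 0 up and 0 down on both adjustments, with Csf1r at 0.85 ± 0.25 (adjusted p = 0.0697), and heme regions had 0 and 0 on both, with Abcg2 at −0.54 ± 0.15 (adjusted p = 0.0572, and 0.24 with 50% reciprocal overlap). Bile acid transport genes had 5 up and 4 down on both adjustments, with Atp8b1 at 1.84 ± 0.28 and the basolateral exporter gene Abcc4 at −1.13 ± 0.25, a call lost without any of 4 single libraries. Iron handling genes had 2 up and 5 down (2 and 4 adjusted over the list alone), with Cp at −1.14 ± 0.23 and the Bmp6 region in 3 of 3 DDC and 0 of 3 standard-diet libraries. AP-1 genes had 7 up and 3 down (10 and 3 adjusted over the list alone), with Fosl2 at 1.61 ± 0.28 and Klf6 at −1.10 ± 0.19. Znrf3 of the pericentral list (3 up, 0 down on both adjustments) rose by 1.04 ± 0.18, and Igf1 of the periportal list (2 up, 0 down on both) by 1.03 ± 0.14. Stellate cell genes had 4 up and 1 down on both adjustments, with Reln at 1.27 ± 0.26 and the matrix gene Dcn at 1.36 ± 0.35, and endothelial genes 2 up and 1 down on both. Cholangiocyte genes had 3 up and 0 down (8 and 3 adjusted over the list alone), with the tight junction gene Cldn4 at 1.27 ± 0.26 and a Prom1 region in 3 of 3 DDC and 0 of 3 standard-diet libraries. Lipid genes had 4 up and 1 down (1 and 0 adjusted over the list alone), inflammation genes 3 and 0 (2 and 0), drug-metabolising genes 3 and 0 (2 and 0) and metallothionein and hypoxia genes 2 and 1 (1 and 1). Cell cycle and ER stress genes each had 1 up and 0 down, and lymphocyte genes 0 and 0, on both adjustments. Of the regions just named, those at Atp8b1, Fosl2, Znrf3 and Igf1 kept their call with standard-diet library 2 as the only one of its group. Those at Abcc4 (−1.28 there), Cp (−0.94), Klf6 (−1.10), Reln (1.18), Dcn (1.503), Cldn4 (1.04), Bmp6 and Prom1 did not pass, with the sign kept, which fewer libraries alone can bring about. The Dcn call was also lost without any of 5 single libraries and the Reln call without DDC replicate 2.

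In total, 4226 regions were called in Fbxl5-deleted mice. Gene ends were again fewer, at 4.20% of risers against 14.5% of other regions and 9.48% of fallers against 14.3% (Fisher's exact test, two-sided, adjusted p = 2.27e-75 and 7.75e-07, again too small because regions are not independent). With 1 standard-diet library left, assumed to vary like the other groups, the count was 1226 (library 2), 1780 (library 3) and 5435 (library 1). It was 2502, 1913 and 2423 without DDC replicate 1, 2 and 3 in turn. It was 1046 with no filter on regions, 7220 against all 6 standard-diet libraries, and 388 and 353 with background or kept fold enrichment as a covariate. Of 51 named regions called here, 35 were called without any single library.

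The B4galt6 region that rose in Fbxl5-deleted mice (chromosome 18, 20757374 to 20757807, 10970 bp from the gene) had a value of 1.81 ± 0.60 (SD, n = 3) on the standard diet and 4.07 ± 0.23 on DDC in these mice. In floxed controls it had 1.65 ± 0.65 and 4.17 ± 0.31. Of 12 regions assigned to B4galt6, 6 rose in controls and 4 in Fbxl5-deleted mice. The rise in Fbxl5-deleted mice was 1.62 and did not pass with standard-diet library 2 as the only one of its group.

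**Figure D3:**
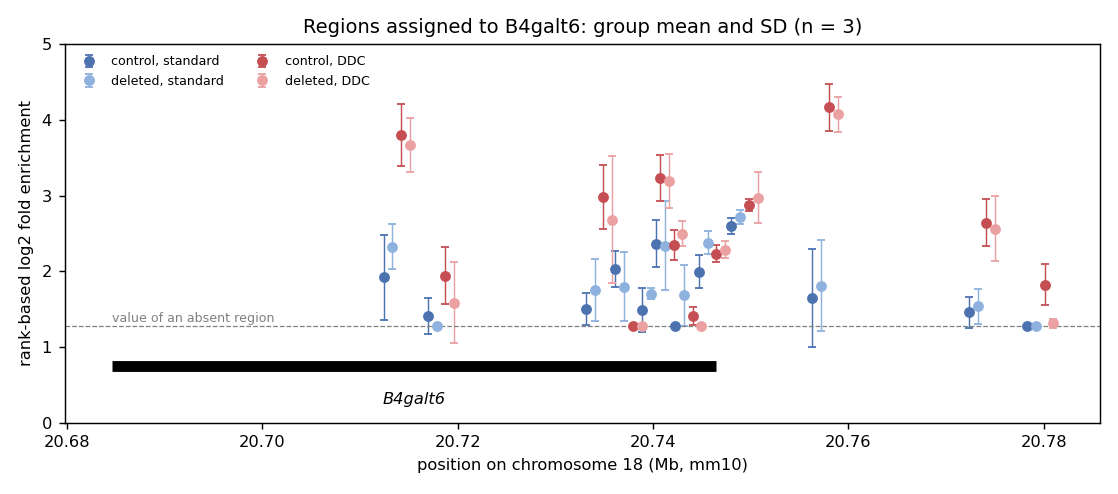
Rank-based log2 fold enrichment (group mean and SD, n = 3) of the 12 regions assigned to B4galt6 along chromosome 18 (Mb, mm10), with points of the 4 groups set slightly sideways of each other, the gene as a black bar and the value of an absent region as a dashed line. At 20757374 the DDC groups lie at 4.17 and 4.07 and the standard-diet groups at 1.65 and 1.81.

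The regions that moved on DDC overlapped between the genotypes. Of 5874 risers in controls 2026 also rose in Fbxl5-deleted mice, where independent lists of these sizes would share 129, and of 3445 fallers 527 also fell, where 29.4 would be shared; 0 regions were called in opposite directions. Across all regions the diet differences of the genotypes had a Pearson correlation of 0.636, regions not being independent replicates. Regions that rose in controls had a median difference of 1.09 in controls and 0.71 in Fbxl5-deleted mice, and those that fell −0.95 and −0.47, with a bias toward controls from their selection there. The design also asks whether genotype altered the response to the diet. No single region passed the test of the difference of the diet effects (limma, 0 of 138620, smallest adjusted p = 0.864, with 7929 at an unadjusted p under 0.05). With 50% reciprocal overlap 66 regions passed (37 higher, 29 lower), and with 500 bp windows 16.

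A diet score that treats the genotypes alike was set up after these counts were seen. It is the mean of the 10091 regions that rose less the mean of the 7533 that fell in the average of both genotypes. The score was −0.87 ± 0.05 (SD, n = 3) in control and −0.82 ± 0.02 in Fbxl5-deleted standard-diet libraries, and 0.78 ± 0.12 and 0.56 ± 0.05 on DDC. The diet effect was 1.64 in controls and 1.37 in Fbxl5-deleted mice, a difference of −0.27 (exact permutation of genotype within diet, two-sided, 400 relabellings, p = 0.015), and it lay between −0.33 and −0.21 without any 1 library. With each library held out of the choice of regions it was −0.42 (p = 0.02, same exact permutation). Regions called in 1 genotype favour that genotype by construction: those called in controls gave effects of 2.12 in controls and 1.23 in Fbxl5-deleted mice, and those called in Fbxl5-deleted mice gave 1.79 and 2.14.

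**Figure D4:**
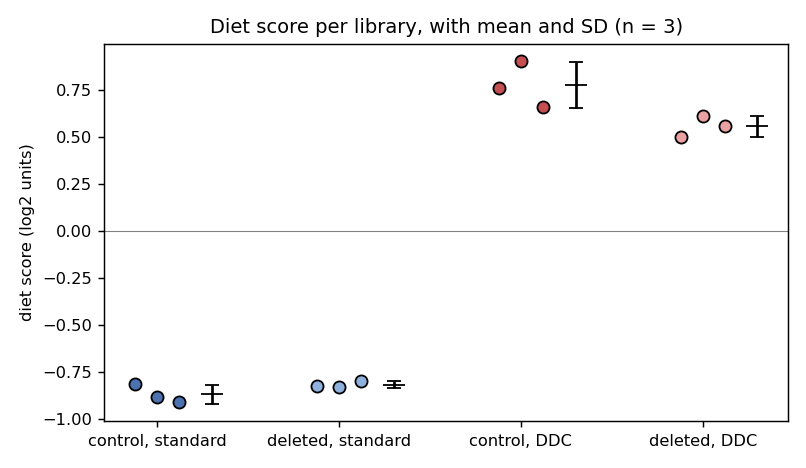
Diet score (mean log2 value of regions that rose on DDC less that of regions that fell) for each library, with group mean and SD (n = 3). The 3 Fbxl5-deleted DDC libraries lie between 0.503 and 0.611, below the 3 control DDC libraries at 0.662 to 0.903.

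On the standard diet, 1 region was called between the genotypes. It lay on chromosome 2 (19796710 to 19797252), with no gene within 50 kb. In Fbxl5-deleted libraries it was lower by a log2 of −0.96 (limma, adjusted p = 0.0378). In the same limma test 11382 regions had an unadjusted p under 0.05. In the simulated data, a genotype comparison without any change gave 3 calls, so 1 call is no more than the test can give without a change. Named members of the lists did not pass. An iron handling region near Slc39a14, a zinc and iron importer gene, was listed in 3 of 3 Fbxl5-deleted and 0 of 3 control libraries (adjusted p = 0.38). An Epas1 region, of the hypoxia factor HIF-2α, was listed in 0 of 3 and 3 of 3. Near Fech the difference was 0.77 ± 0.26 (adjusted p = 0.414), near the heme oxygenase gene Hmox1 −0.32 ± 0.11, in the bile salt export pump gene Abcb11 −0.86 ± 0.27, near Cyp2b10 0.69 ± 0.21 and in Reln −1.06 ± 0.26. The 20 lists had 0 regions up and 0 down, with 1 Reln region down adjusted over the list alone, and no list shifted, the closest being hepatocyte identity (camera, median 0.07, adjusted p = 0.0837). The 1 call was lost without any 1 of the standard-diet floxed control libraries and without library 1 or 3 of the Fbxl5-deleted group, where 0 regions passed, and without library 2 of that group 67 did. With 50% reciprocal overlap 128 passed (41 higher, 87 lower), with 500 bp windows 24 and with no trend and no robust setting 11.

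On DDC, the comparison the series is named for, 0 of 138620 regions differed between Fbxl5-deleted and control hepatocytes (limma, smallest adjusted p = 0.157); 7991 had an unadjusted p under 0.05. With 50% reciprocal overlap, where narrow peaks can count as absent, 107 regions passed (13 higher, 94 lower), and with 500 bp windows 15. The differences at named regions were −0.43 ± 0.13 near the iron-responsive gene Atoh8, −0.81 ± 0.28 near Smad6, and −1.02 ± 0.25 in the cystine transporter gene Slc7a11. They were 0.61 ± 0.18 near Akr1d1, of bile acid synthesis, 0.69 ± 0.24 near the xenobiotic receptor gene Nr1i2, and 0.83 ± 0.19 in Acacb. Values of −0.91 ± 0.29 near Acta2, 0.97 ± 0.22 near the endothelial factor gene Erg, 0.92 ± 0.22 near Anxa3 and 0.57 ± 0.18 near Cyp3a11 were found as well. Their adjusted p ranged from 0.349 upward. Regions near Txnrd1 and in Abcg2 and Slc1a2 were listed in 0 of 3 Fbxl5-deleted and 3 of 3 control libraries without passing. No list shifted, the lowest adjusted p being 0.302 for hepatocyte identity (median 0.04) and for stellate cell and matrix genes (median −0.06). Of list regions 0 passed over all regions, and 1 endothelial region up and 1 region in each direction of the pericentral list passed adjusted over the list alone. Averaged over both diets (6 libraries against 6), 0 regions were higher and 1, the same chromosome 2 region, was lower (−0.69 ± 0.09, adjusted p = 0.0334). In simulated data for the diet in controls, the test recovered 22% of changes of log2 1 and 61% of log2 2, so genotype differences of such sizes in single regions can have been missed.

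Which regions were listed at all was also compared between groups. In floxed controls 5406 regions were in 3 of 3 DDC and 0 of 3 standard-diet lists and 2462 the reverse, in Fbxl5-deleted mice 3419 and 913. Between genotypes 355 were in all Fbxl5-deleted and no control list on the standard diet and 1236 the reverse, and on DDC 549 and 1009. The direction on the standard diet turned with all deposited peaks (1281 and 683) and was lost without Fbxl5-deleted replicate 1 (1744 and 1738). Over the 10 splits of the 6 libraries compared, the diet totals of 7868 and 4332 exceeded those of all other splits (at most 1246 and 1514). The genotype totals of 1591 and 1558 did not, as another split gave 1602 on each diet. These genotype counts thus lay within what other groupings of the same libraries gave. The mean Jaccard index (shared over combined base pairs) of library pairs was 0.627 within and 0.574 between the diets in controls, 0.578 and 0.550 in Fbxl5-deleted mice, and 0.581 and 0.576 (standard diet) and 0.624 and 0.620 (DDC) within and between genotypes. The real split had the largest gap of the 10 in all 4 comparisons, a share of 0.1, the smallest this exact permutation can give. With all deposited peaks the share for genotype on the standard diet was 0.2.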

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

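The differences of diet effects in library values were not among the planned tests. They, the diet score, the tests of explanations and the statements of what other splits would show were chosen after the results they bear on had been seen. Of the explanation tests, 5 were changed after a first version had been computed.

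Genotype differences that were not alike on both diets appeared in 7 values. The difference in listed peaks between Fbxl5-deleted and control libraries was −15531.7 on DDC and 79879.7 on the standard diet, so that the effects differed by −95411 (exact permutation, two-sided, p = 0.025). In the same exact permutation tests all lines of the lists differed by −92724 (p = 0.025) and covered sequence by −15.5 Mb (p = 0.025). The share of kept peaks at gene ends differed by 1.00 percentage points (p = 0.025), by 1.55 with a wider distance to the ends (p = 0.035) and by 5.26 over all deposited peaks (p = 0.015), and the diet score by −0.27 (p = 0.015, all exact permutation). Adjusted over the 39 tests of library values, the share within the wider distance has an adjusted p of 0.114 and the other 5 library values 0.0886, and the score, set up later, was not adjusted. Outside the regions compared, peaks on unplaced and other contigs made up 0.238% of the lines in Fbxl5-deleted and 0.18% in control lists (exact permutation, p = 0.02, adjusted p = 0.0886). Fbxl5-deleted standard-diet library 1 held 0.359%, and without it the difference was 0.0366 in place of 0.0581 percentage points.

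The many peaks of Fbxl5-deleted standard-diet libraries 1 and 3 set the difference in listed peaks. In these 2 libraries the background was so low that the Poisson probability of more than 2 fragments was 0.0268 and 0.0402, below the 0.05 that the lists were called with, against at least 0.0592 in the other 10. They held 153722 and 136514 peaks of 3 fragments or less, against at most 10672 in any other library. A genotype effect as the whole cause is argued against by the other 4 Fbxl5-deleted libraries, which held 8551 to 9907 such peaks, within the 6126 to 10672 of the controls. Low background passing the caller's threshold may therefore account for the excess, while why these 2 libraries had low background was not tested.

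Regions that differed with the diet could reflect the higher background of the DDC libraries. With the background as a covariate the diet difference of the held-out score was 1.71 ± 0.149 (95% 1.36 to 2.06) in place of 1.61. In that score each library was held out of the choice of regions. Backgrounds of the diets did not overlap, the highest on the standard diet being 1.00 and the lowest on DDC 1.03 fragments. The fit therefore rests on differences within groups and cannot exclude background as the cause. The libraries with these values had held-out scores of −0.86 and 0.68. With this covariate the called regions went down to 3223 in controls and 388 in Fbxl5-deleted mice. Their median SE widened from 0.249 to 0.338 and from 0.247 to 0.353, while their median size was 1.06 in place of 1.03 and 1.03 in place of 1.08. A lower share of hepatocytes cannot be told apart from a change in other cells: hepatocyte identity regions moved by −0.125 and cholangiocyte regions by 0.0316 (exact permutation, adjusted p = 0.0217 and 0.039), as a lower share would give, while lymphocyte regions at −0.075 and endothelial regions at 0.0251 did not pass (adjusted p = 0.122 and 0.242). Macrophage and stellate markers moved up by 0.168 log2 relative to cholangiocyte, endothelial and lymphocyte markers (exact permutation, p = 0.005, adjusted p = 0.0217 over 13 tests), but the latter started higher, at 2.22 against 2.00, where added cells would show less. A response of hepatocytes to the diet stays open.

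The smaller diet score of Fbxl5-deleted mice may come from the standard-diet libraries that stood apart, from lower enrichment, from the mix of cells or from the genotype. Among the DDC libraries alone the difference was −0.22, against 0.05 on the standard diet, and with each library held out of the choice of regions −0.26 against 0.16, with every Fbxl5-deleted DDC library below every control (by as little as 0.726 against 0.727 when held out), which argues against the standard-diet libraries as the whole cause. With the fold enrichment of kept peaks as a covariate the difference of effects was −0.28 ± 0.0757 (95% −0.46 to −0.11), and −0.43 ± 0.169 (95% −0.83 to −0.03) when held out, which argues against enrichment as the whole cause on this score. A different mix of cells was not tested for this score and cannot be told apart from the genotype. Fbxl5-deleted less control, within diet, hepatocyte identity regions differed by 0.0588 and stellate cell regions by −0.0516 (exact permutation, adjusted p = 0.122 and 0.119). Macrophage regions differed by −0.0384, lymphocyte regions by −0.0555, cholangiocyte regions by 0.00561 and endothelial regions by −0.002. The genotype remains as a hypothesis, with an exact permutation p of 0.015 (0.02 when held out), since the score was set up after the counts were seen, no single region passed, and library batches are not given in the sources used here. An earlier form of the test, the ratio of called regions between controls and Fbxl5-deleted mice, was 2.21 against each group's own standard diet and 1.90 against all 6 standard-diet libraries.

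Other splits of the same libraries were counted for each model result. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For called regions the real split and the highest other split gave 9319 and 0 (diet in controls; 1 split as large, the real one), 4226 and 1 (diet in Fbxl5-deleted mice; 1 split), 1 and 1 (genotype on the standard diet; 2 splits) and 0 and 0 (genotype on DDC; 10 splits). For called gene lists they gave 5 and 0 (1 split), 3 and 10 (3 splits), 0 and 7 (10 splits) and 0 and 2 (10 splits), in the same order. The split with 10 lists, over 3 times the real count, set standard-diet libraries 1 and 3 with DDC library 1 against the others. It points to a structure among these libraries or to a preset correlation that is too small, which were not tested apart. For the difference of diet effects the real split gave 0 regions and the highest other split 1. Where the real count is 0, as here (100 of 100 splits), every split reaches it, so these counts decide nothing.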

How the results depend on the processing

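Leaving out pairs of Fbxl5-deleted standard-diet libraries, leaving out libraries for stronger peaks, the background and fold enrichment covariates and the comparison with all 6 standard-diet libraries were chosen after the data were seen; all other alternatives were planned. In simulated data with 3 libraries per group and few changed regions, differences of up to about 2-fold in single regions were mostly missed, and 4-fold changes in part. Where no reason is given below, the cause was not tested.

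Called regions for the diet in controls (9319) and in Fbxl5-deleted mice (4226), and for genotype on the standard diet (1), on DDC (0) and the difference of diet effects (0), moved by over 1.5 times as follows. With the strongest N/2 peaks 5963 were called in controls. With regions in all 12 lists, so that fewer were tested, 3388 and 2109 were called for the diet; with no filter, so that more were tested, 3151, 1046 and, for genotype on the standard diet, 0. With 50% reciprocal overlap the 5 counts were 3714, 1145, 128, 107 and 66, and with 500 bp windows genotype gave 24 and 15 and the difference of effects 16. Ranking by −log10 p gave 0 and 1 for genotype, and normal scores 0 and 1. With no trend and no robust setting genotype on the standard diet gave 11. With the compared groups alone, thus fewer samples, 1463 were called in Fbxl5-deleted mice and 0 for genotype on the standard diet. With 1 Fbxl5-deleted standard-diet library left, assumed to vary like the other groups, these were 1226 and 0 without libraries 1 and 3, 1780 and 272 without 1 and 2, and 5435 and 2105 without 2 and 3; 845 of the 1226 were among the 4226. The background covariate gave 3223, 388 and 0, and the fold enrichment covariate 4335, 353 and 0. Against all 6 standard-diet libraries 7220 were called in Fbxl5-deleted mice.

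Leaving out each library in turn, which leaves fewer samples, the counts lay between 4771 (without floxed_control_DDC replicate 2) and 7755 in controls, between 1913 and 3650 in Fbxl5-deleted mice, between 0 and 67 for genotype on the standard diet (67 without Fbxl5_deleted_standard replicate 2) and between 0 and 1 on DDC.

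The replicate number used as a block left the calls near the unblocked ones, at 8970, 3970, 2, 0 and 0 regions and 5, 3, 0 and 0 lists. Same-numbered libraries deviated together only slightly, with residual correlations of −0.024 to 0.054 over 18 pairs (median 0.014). The 36 pairs with different numbers had −0.043 to 0.025 (median −0.004). The numbers were not taken as pairing.

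For gene lists (5 called in controls, 3 in Fbxl5-deleted mice) an estimated correlation gave 0 and 0, gene-end regions 2 and 6, all deposited peaks 1 and 1, none of them among the 5 and 3, and leaving out standard-diet libraries 1 and 3, 1 and 2, or 2 and 3 gave 0, 2 and 7 in Fbxl5-deleted mice. With all deposited peaks some lists turned direction: in controls bile acid synthesis (adjusted p = 0.884) and stellate cell and matrix (0.232), in Fbxl5-deleted mice antioxidant (0.974) and bile acid synthesis (0.614).

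The diet difference in peaks per library was 13989.7 at a −log10 q of at least 5, 9488.83 at a fold enrichment of at least 5, and 36804.7 without standard-diet libraries 1 and 3; it ran from −18302.3 to 9433.42 with each library left out. The genotype difference was −8312, −6428.17 and −4564 in these settings and 22807.2 to 50543 with each library left out. At a −log10 q of at least 5 it ran from −11184.8 to −5697.83 with each library left out, and at a fold enrichment of at least 5 from −8311.92 to −4257.92, and was −2660.67 without standard-diet libraries 1 and 3. The share of peaks at gene ends differed by diet by 0.0380 with all deposited peaks, and with each library left out by −0.518 to −0.306 (diet) and −0.324 to −0.111 (genotype).

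Regions in all lists of a group and none of the other (7868, 4332, 1591 and 1558) were 4654, 2763, 807 and 759 with the strongest N/2 peaks, 25882 (diet) and 19613 (genotype) without standard-diet libraries 1 and 3, where the 1 list left makes up its whole group, and for genotype on DDC 2338 with 50% reciprocal overlap and 2439 with all deposited peaks. With each library left out, and so fewer lists needed, they were 10732 to 13383, 7231 to 8339, 3482 to 5413 and 3481 to 4154.

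Single regions turned sign with 50% reciprocal overlap at Csf1r (−0.90) and Pfkfb3 (1.06) in controls, Abcg2 (0.24) in Fbxl5-deleted mice, Tfeb (−0.54) for genotype on the standard diet and 1 other region (0.42) for genotype on DDC, and with 500 bp windows at Pinx1 (0.16) in Fbxl5-deleted mice. Without standard-diet libraries 1 and 3, Col1a2 (0.076) and the Fbxl5 regions at 43781400 (−0.10) and 43745212 (0.087) turned sign for genotype on the standard diet. Of 59 named regions called in controls 37 were called in every alternative and 54 without any single library; of 51 in Fbxl5-deleted mice these were 8 and 35. The 8 were those at Bloc1s6, Fam180a, Il33, Papss1, Elmo1, Eif2s1, Tmem45a and Pabpc4l.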

Other observations

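The test at gene ends was planned; the counts of regions per gene and the tests at Alb were chosen after the data were seen, and the Alb test was computed in 3 forms.

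Gene ends of AP-1 and immediate early genes, many of which encode transcription factors induced within minutes of a stimulus, moved down with DDC although the whole list did not. Their 37 gene-end regions had a median of −0.27 in controls and −0.31 in Fbxl5-deleted mice (camera, adjusted p = 7.5e-05 and 6.44e-05), with adjusted p = 0.55 and 0.348 with an estimated correlation. In each genotype 3 gene-end regions fell, at Atf3 and Klf6, and 0 rose. The lowest adjusted p among the other splits of the same libraries was 0.0141 and 0.0210. Between genotypes the list had an adjusted p of 0.0924 on the standard diet and 0.695 on DDC, the lowest other splits giving 0.122 and 0.151. Gene ends of macrophage genes moved up (camera, adjusted p = 0.00369 and 0.000854), with adjusted p = 0.445 and 0.285 with an estimated correlation. In Fbxl5-deleted mice those of iron handling (0.0203), antioxidant (0.00169), bile acid transport (0.0301) and hepatocyte identity genes (camera, adjusted p = 0.0110) moved down too, so the fall was not particular to AP-1 genes there. With an estimated correlation these 4 had an adjusted p of 0.348 to 0.515.

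Regions that rose on DDC gathered at a few genes in floxed controls. These were 5 of 7 regions of the splicing factor gene Smndc1, 6 of 12 of B4galt6 and 5 of 8 of the thyroglobulin gene Tg (hypergeometric test, Benjamini-Hochberg over 12160 genes, adjusted p = 0.0185, 0.0185 and 0.0208). In Fbxl5-deleted mice 5 of 30 regions of Cmah, of sialic acid synthesis, fell (adjusted p = 0.0465), and none gathered among risers at this threshold. Neighbouring regions are not independent, so these p-values are too small.

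A region 10342 bp from the albumin gene Alb (chromosome 5, 90449725 to 90450528) had a value of 4.07 ± 0.19 (SD, n = 6) in Fbxl5-deleted and 3.52 ± 0.16 in control libraries. It was picked for this difference, as the 8th of 138620 regions by the genotype effect averaged over diets, and did not pass there (limma, adjusted p = 0.225). A hypothesis is that copies of albumin enhancer and promoter sequence in the Cre transgene, whose sequence the labels do not give, may add fragments at this region. The region over the start of the Alb span, not picked for its difference, differed by 0.30 (exact permutation, p = 0.07). Its difference was 0.35 relative to the other 11 Alb regions (p = 0.045 in the same exact permutation test), while those differed by −0.05 (p = 0.32). As only 1 of the 2 forms was under 0.05, this does not decide between transgene copies and a change at the gene itself.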
